A study of Yarrowia lipolytica with 2 samples.

How the data were processed

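RNA libraries of the yeast Yarrowia lipolytica strain Y-2 were sequenced, 1 from a culture grown without ochratoxin A (OTA) and 1 from a culture grown with it. Both were grown for 48 h in NYDB medium, and the treated culture received 1 µg/mL OTA, per the labels' protocols. The label that describes the control names another mycotoxin, citrinin, as the agent that was left out; the treatment label of the same sample says that no OTA was added, and the sample was grouped by that label. Libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols; no strand setting is given, so reads of overlapping genes on opposite strands could not be told apart here.

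The deposited files have the column layout of RSEM gene tables, per the file headers, and their gene identifiers follow the naming of the de novo assembler Trinity. A row is therefore an assembled gene, a group of 1 or more contigs, and not an annotated locus of the genome. The authors deposited expected counts, which are estimated counts that need not be whole because a read that matches several contigs is shared among them. The TPM values that the authors deposited sum to the same fixed total in both libraries, and the authors' deposited FPKM values are per kilobase of effective length. The file headers list an effective length, taken here as the gene length less an allowance for the sequenced fragment. Versions and settings of RSEM and Trinity are not given in the sources used here. The submitters' processing notes also list Bowtie 0.12.2 and the genome build mm8, a mouse build to which no identifier in the files refers; neither was used here.

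Gene names could not be attached. The reference table of Yarrowia lipolytica CLIB89(W29), assembly ASM176148v1, was searched for the identifiers and matched 0 of 13896. The 34 functional gene lists and 23 locus tags that were fixed before the data were examined could for that reason not be read, and no pathway is described. The rule for named genes, fixed at the same time, allowed in this case the identifiers of at most 2 genes with the highest and 2 with the lowest ratio among genes with at least 50 counts; other features are described by their length and counts, and those were chosen after their values were seen. No genome coordinates were used here.

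Expected counts were rounded to whole numbers and scaled by effective library sizes from edgeR 4.0.16 (TMM). A gene without a count is one whose expected count rounded to 0, so it may hold an expected count of up to 0.5. The log2 ratio of OTA to control was computed with 0.5 added to each count. A feature was called at least 2-fold apart when it had at least 20 counts over both libraries and its ratio reached 2 or its reciprocal. Each ratio was given an exact 95% interval (Clopper-Pearson, on the share of the counts that fell in the OTA library). Intervals and limits cover counting error only, with reads taken as independent. PCR copies are not independent molecules, so the intervals may be too narrow. The sharing of reads among contigs is not covered either. For a gene without a count in 1 library, a lower bound of the fold was computed against 3 counts in that library. With 1 library per group there was no replicate check and no test of the treatment: counts of features past the 2-fold limit describe these 2 libraries by a fixed rule of size, and no p-value was computed.

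The summing of counts over clusters was added after the data were seen. A cluster holds the genes whose Trinity identifiers are the same up to the gene number, which marks contigs built from connected reads. A count was taken as whole when it lay within 0.02 of a whole number. The calculation was tested on simulated data: Poisson counts were drawn for the real genes at the real library sizes. With equal composition, 94 of 10215 simulated genes and 56 of 7903 simulated clusters were at least 2-fold apart. The simulated pairs hold counting error only, so they do not show how far 2 untreated cultures or library preparations would differ. With changed genes added, 99.0% of 99 genes changed 4-fold and 100.0% of 99 genes changed 8-fold passed the 2-fold limit.

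Alternatives were scaling by total counts, by DESeq2 1.42.0 size factors or by the total without the 100 most abundant genes, ratios of TPM or FPKM with 1 added, other count minimums, another prior count, a stricter size limit, a minimum effective length of 300 bases, division by effective length, and restriction to genes with whole counts. Calculations were run in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.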

Results

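The transcriptome of Yarrowia lipolytica Y-2, a strain of an oil-storing yeast, was compared between a culture grown with ochratoxin A and a culture grown without it. Ochratoxin A is a mycotoxin made by Aspergillus and Penicillium moulds, in which a chlorinated isocoumarin is joined to phenylalanine. The question the design addresses is which transcripts differ in abundance when the yeast grows with the toxin. The control group and the OTA group each held 1 library, sampled after 48 h, and the OTA culture received 1 µg/mL of the toxin. There were no replicates, so every difference below is between 2 libraries and its error covers counting alone.

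The control library held 23635704 counts and the OTA library 19797779, assigned to 13896 assembled genes made of 20121 contigs. A gene had a median length of 1417 bases, and the lengths ran from 301 to 17377 bases. After rounding, 12967 genes had at least 1 count in the control library and 12745 in the OTA library, and 556 had none in either. At these depths a gene without a count may still be present at up to 0.127 CPM (library-scaled counts) in the control library and 0.152 in the OTA library. The genes fell into 10090 clusters of connected contigs, of which 6962 held 1 gene and 3128 held 2 or more.

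The most abundant transcripts were largely shared between the libraries. Of the 5 genes with the highest TPM in each library, 4 were shared, and of the 100 highest, 85 were. The most abundant gene of the control library, a single contig of 1156 bases, had a TPM of 25436 there and 16745 in the OTA library, a count ratio of 0.682 (95% counting interval 0.678 to 0.686). The most abundant gene of the OTA library, 694 bases long, had a TPM of 23777 in the control and 25308 in the OTA library, a count ratio of 1.08 (1.07 to 1.09). A gene of 331 bases stood eighth in the control library with a TPM of 9831 and second in the OTA library with 21838. These ranks rest on a short effective length, by which TPM is scaled. The gene of 331 bases held 13087 counts in the control and 20538 in the OTA library. The gene of 694 bases held 161436 and 141446. For the gene of 331 bases, TPM differed 2.22-fold and counts 1.94-fold (1.89 to 1.98). The counts of the genes of 694 and 331 bases were fractional, so reads were shared with another gene of the cluster. Ranked by counts and not by TPM, the top 10 genes of the control library took 15.6% of its counts (Wilson 95% interval 15.55% to 15.58%). The top 10 of the OTA library took 13.3% (13.33% to 13.36%). Across the 13340 genes with a count in either library, log2(CPM + 1) had a Pearson correlation of 0.98 and a Spearman correlation of 0.96; this is across genes, which are not independent replicates.

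At the level of assembled genes, 1260 of the 10228 with at least 20 counts were at least 2-fold apart, 711 higher and 549 lower in the OTA library, and 8968 were not. Scaling by the total without the 100 most abundant genes turned this balance, to 610 higher and 678 lower. A simulated pair of libraries with equal composition put 94 of 10215 genes past the same limit by counting error alone. For 381 higher and 209 lower genes the whole counting interval lay beyond 2-fold. The differences were more frequent among genes whose counts were shared. Of 4413 genes with a fractional count, 18.6% were at least 2-fold apart, against 7.58% of 5815 genes with whole counts in both libraries. These 2 groups were not matched for depth. With at least 500 counts, 5.70% of all genes and 4.90% of clusters were at least 2-fold apart.

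The genes at the extremes had counts in 1 library only. TRINITY_DN1248_c0_g1, of 6913 bases, had 0 counts in the control and 403 in the OTA library, at least 166-fold higher against a limit of 3 counts. TRINITY_DN3525_c0_g1, of 6942 bases, had 0 and 177, at least 72.8-fold higher. In the other direction, TRINITY_DN1882_c0_g1, of 3596 bases, had 757 counts in the control and 0 in the OTA library, at least 204-fold lower. TRINITY_DN505_c0_g2, of 1591 bases, had 689 and 0, at least 186-fold lower. Each had a partner of nearly its own length in the same cluster that was counted in both libraries. The partner of TRINITY_DN1248_c0_g1 measured 6914 bases and held 3691 counts in the control and 2759 in the OTA library. The partner of TRINITY_DN3525_c0_g1 measured 6944 bases and held 7588 and 5015. The partner of TRINITY_DN1882_c0_g1, 3590 bases long, held 1170 and 2621, and the more abundant partner of TRINITY_DN505_c0_g2, 1595 bases long, held 3918 and 4028.

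Summed over the cluster, these differences were lost or turned. The cluster of TRINITY_DN1248_c0_g1 had a ratio of OTA to control of 1.06 (1.01 to 1.11), and that of TRINITY_DN505_c0_g2 a ratio of 1.01 (0.970 to 1.06). The cluster of TRINITY_DN3525_c0_g1 was lower in the OTA library, at 0.844 (0.815 to 0.875), and that of TRINITY_DN1882_c0_g1 higher, at 1.68 (1.58 to 1.78). In all, 165 genes with at least 20 counts lacked a count in 1 library, 91 of them in the OTA library and 74 in the control, and all 165 lay in clusters of 2 or more genes. No cluster with at least 20 counts lacked counts in either library. Of the 160 clusters that held those genes, 145 were less than 2-fold apart. Because the gene-level counts depend on how reads were shared, the comparisons by abundance and of the highest and lowest features use cluster sums.

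**Figure D1:**
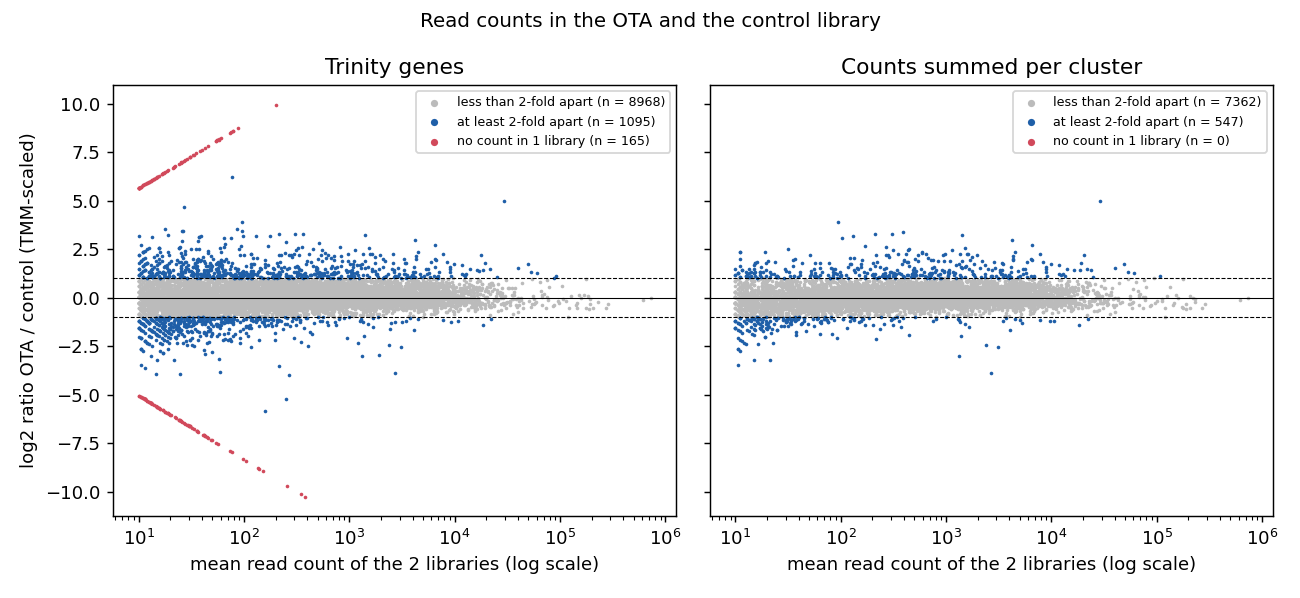
Log2 ratio of OTA to control (TMM-scaled, 0.5 added to each count) against the mean read count of the 2 libraries on a log axis, for assembled genes (left) and for counts summed per cluster (right), with at least 20 counts; each point is a gene or a cluster and dashed lines mark 2-fold. The 165 red genes without a count in 1 library form the outer arms on the left, where their height is set by the added 0.5, and none remain on the right.

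Of 7909 clusters with at least 20 counts, 350 were at least 2-fold higher and 197 at least 2-fold lower in the OTA library, and 7362 were neither. A simulated pair of equal composition gave 56 of 7903 by counting error alone. The quartiles of the log2 ratio were -0.25 and 0.31 around a median of 0.01. Scaling by the total without the 100 most abundant genes, which shifted all log2 ratios by -0.11, gave 283 higher and 269 lower clusters.

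The balance of higher and lower clusters differed between abundance classes, set by the mean scaled CPM of both libraries. Among the 676 clusters below 1 CPM with at least 20 counts, 46 were at least 2-fold higher and 84 lower, and the median log2 ratio was -0.22. These clusters hold few counts each, so counting error alone can put some past the limit. Length was not held equal between the classes. Of all clusters, those below 10 CPM had a longest gene with a median of 680 bases, against 2390 bases in the others. From 1 to 10 CPM the numbers were 83 and 76. From 10 to 100 they were 142 and 23, and from 100 to 1000 they were 69 and 14. Of the 134 clusters at 1000 CPM or more, 10 were higher and 0 lower. Among the 5024 clusters with at least 500 counts, 211 were at least 2-fold higher and 35 lower. The simulated pair gave 0 past the limit, which was nearly certain at these counts, since it holds no variation between cultures. For 169 of the higher and 24 of the lower clusters the whole counting interval lay beyond 2-fold.

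The most elevated cluster with at least 500 counts was a single gene of 1 contig, 1917 bases long, whose counts were whole. It had 2170 counts in the control and 55991 in the OTA library, which is 90.3 against 2875 scaled CPM and a 31.8-fold difference (30.5 to 33.2). The next, with a longest gene of 1967 bases, rested on 82 and 697 counts and differed 10.4-fold (8.33 to 13.4). The third, with a longest gene of 2096.5 bases on average over its contigs, had 69 and 545 counts and differed 9.69-fold (7.58 to 12.7). A cluster with a longest gene of 6336 bases had 330 and 2504 counts, a 9.35-fold difference (8.34 to 10.5). A cluster of 2 genes, the longer of 4940 bases, had 1126 and 7289 counts and was 7.98-fold higher (7.50 to 8.51). A gene of 2579 bases with whole counts had 2103 and 11028 counts and was 6.47-fold higher (6.18 to 6.78).

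Among clusters with at least 500 counts, the 5 with the lowest ratio of OTA to control were single genes of 1 contig with whole counts. A gene of 3461 bases had 5112 counts in the control and 276 in the OTA library, 15.0-fold lower (13.3 to 17.0). A gene of 1098 bases had 2406 and 239 counts and was 8.14-fold lower (7.14 to 9.36). Genes of 5850 and 1683 bases were 5.85-fold (5.42 to 6.32) and 5.52-fold lower (5.07 to 6.02). A gene of 2948 bases, with 2305 and 470 counts, was 3.97-fold lower (3.60 to 4.40). Functions cannot be given for these genes, because their identifiers are not paired with names here.

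**Figure D2:**
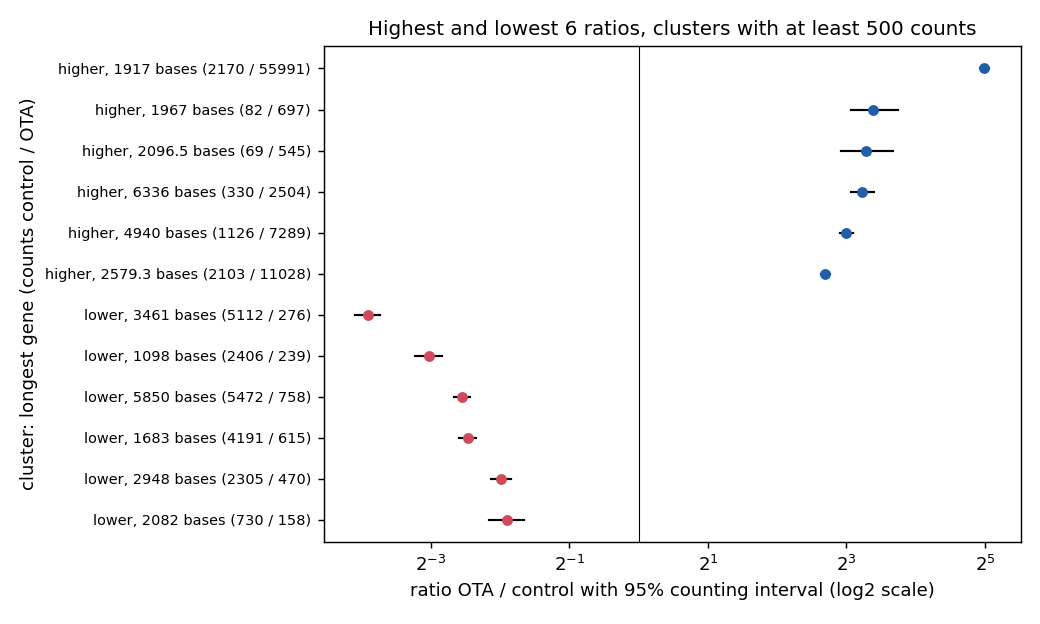
Ratio of OTA to control (log2-scaled axis) for the 6 clusters with the highest and the 6 with the lowest ratio among those with at least 500 counts; points are ratios, bars are exact 95% counting intervals from 1 library per group, and labels give the length of the longest gene and the counts in the control and OTA library. The top cluster lies at 31.8, apart from the next at 10.4, and the lowest at 15.0-fold below the control.

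The libraries also differed in the fragment length that the effective lengths imply. It was compared over assembled genes and so includes shared reads. The allowance subtracted from a gene's length was 244.26 bases in the control and 261.18 bases in the OTA library. Among the 144 genes of 300 to 400 bases with at least 20 counts, 5 were at least 2-fold higher and 31 lower, with a median log2 ratio of -0.34. The median was 0.03 in the 8267 genes above 1000 bases. After each count was divided by the effective length of its library, the short genes had a median of -0.08, with 10 higher and 19 lower.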

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

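The cluster sums, and with them every alternative run on clusters, the restriction to whole counts, the division by effective length and the total without the 100 most abundant genes, were chosen after seeing the data; the other gene-level alternatives were fixed before the data were examined. No paired analysis was possible because each group has 1 library. The alternatives for the functional gene lists were not run, since no list could be read. Against 1260 genes at least 2-fold apart (711 higher, 549 lower), log2(TPM + 1) gave 744 (434, 310) and log2(FPKM + 1) 608 (379, 229). No filter beyond 1 count gave 2852 (1386, 1466) and at least 100 counts 604 (420, 184). A whole interval beyond 2-fold gave 590 (381, 209), a 4-fold limit 362 (189, 173), whole counts 441 (262, 179) and cluster sums 547 (350, 197). Fewer or more features tested and the stricter limits account for part of this by construction. So does the 1 added to TPM and FPKM, which draws the ratios of low values towards 1. The remaining cause was not tested. Against 547 clusters (350 higher, 197 lower), log2(TPM + 1) gave 361 (113 lower), log2(FPKM + 1) 318 (78 lower), no filter 1496 (707, 789), at least 100 counts 353 (74 lower), a prior count of 5 gave 112 lower, a whole interval beyond 2-fold 241 (203, 38) and a 4-fold limit 68 (47, 21). The other scalings kept each of these counts within 1.5 times, but the total without the 100 most abundant genes turned the balance of genes to 610 higher and 678 lower. The Pearson correlation of 0.98 was 0.959 on log2(TPM + 1) and 0.989 over clusters; the Spearman correlation of 0.96 was 0.927, 0.983 over clusters and 0.971 with at least 20 counts. Summing over the cluster turned the direction of TRINITY_DN3525_c0_g1 (log2 ratio -0.24) and TRINITY_DN1882_c0_g1 (0.75), and left TRINITY_DN505_c0_g2 at 0.017, with an interval that includes no difference. TPM, FPKM and another prior count were not run for the genes at 0 in 1 library, where the added constant would set the ratio. The 6 highest and 6 lowest clusters with at least 500 counts kept their direction and stayed past 2-fold in 72 of 72 alternatives. That outcome was nearly fixed in advance, because these clusters were picked for their large ratios and the alternatives move such ratios little. Depth limits the clusters below 1 CPM, where few counts separate 2-fold from equal.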

Other observations

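Of the tests in this part, the 2 on where genes without a count lie among the clusters and the one on the choice of scaling were chosen after the result had been seen, in whole or in part; the predictions of the rest were written before their values were seen, although the measures they use (division by effective length, clusters, whole counts) were themselves chosen after seeing the data.

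Few genes assembled as several contigs differed in mean length between the libraries, a measure that does not move when contigs of like length exchange reads. Of 1605 such genes with at least 500 counts, 4 had an abundance-weighted length more than 20% longer in the OTA library and 4 more than 20% shorter, and the median change was 0.167%. The furthest changes were 39.1% and -59.2%. For 7 of those 8 genes the counts differed less than 2-fold.

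The assembly held more features than the yeast has annotated genes. The reference table of strain W29 lists 8689 genes, 7918 of them protein-coding, against 13896 assembled genes, whose lengths sum to 25.5 Mb, and 10090 clusters. Clusters below 10 CPM made up 48.6% of all clusters but held 0.966% of the counts in the control and 0.939% in the OTA library. Their longest gene had a median of 680 bases, against 2390 bases in the 5186 clusters at or above that level.

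The first pattern is the 165 genes with at least 20 counts and none in 1 library. Poisson sampling at equal composition gave 0 such genes. The minimum of 20 counts made that outcome nearly certain, so the simulation is no separate evidence about depth. At that minimum, counting error alone would rarely leave 1 library at 0. If whole genes had been switched on or off with OTA, they would be found in clusters of 1 gene about as often as all tested genes, 47.9% of which lie there; the share was 0%. A candidate explanation is that reads shared between contigs of a cluster were assigned differently in each library. No sequences were compared. In 2465 of 2465 clusters of several genes with fractional members the fractions sum to whole counts in both libraries. These sums cover all such clusters and do not show how reads of the 165 genes were assigned. Of those genes, 165 of 165 lie in clusters of several genes, and 153 have a fractional count. The other 12 had counts within 0.02 of a whole number, where random fractions would put 8.25 of 165, and only 3 of them were exactly whole; these 3 show no direct sign of shared reads, and for them, as for copies or alleles of which 1 changed with OTA, the explanation stays open.

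The second pattern is the lower counts of short genes in the OTA library. The median log2 ratio of genes of 300 to 400 bases differed from that of genes above 1000 bases by -0.37 (interval over 2000 resamples of genes -0.505 to -0.168). After division by effective length the difference was -0.112 (-0.334 to 0.029). Longer sequenced fragments in the OTA library may account for much of it, but the remainder just missed the bound of 0.1 set for that explanation. A lower abundance of short transcripts with OTA cannot be told apart from it, since the interval spans both predictions.

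The third pattern is the excess of higher over lower clusters among those with at least 500 counts, 211 against 35. Over 4 scalings the share of higher clusters was 77.1% to 85.9%, so the choice among these did not make the excess. They lie close together: the one furthest from TMM shifted log2 ratios by -0.11. A larger difference in scale was not tested. Reads were shared within clusters, where fractions summed to whole counts in 2465 of 2465 clusters of several genes with fractional members. Such sharing leaves a cluster sum as it is, so it could not make the excess. The clusters of 1 gene with whole counts, where 84.1% of the clusters past 2-fold were higher, are therefore no separate test of it. An effect of OTA and a difference between 2 cultures or library preparations cannot be told apart, because there is 1 untreated library and none to set beside it. That induction outnumbers repression among abundant transcripts of OTA-grown cells is therefore only a hypothesis, which replicate cultures could decide.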
